A study of Mus musculus with 2 samples.

How the data were processed

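RNA of poly(I:C)-treated WT and Oasl1-/- macrophages was measured on 1 Affymetrix Mouse Gene ST array per genotype, each with RNA mixed from 3 samples, per the labels. The array values are log2 values as deposited by the authors, summarised per probe set. The submitters' processing notes name GCOS and RMA, a method that corrects the background, normalizes the arrays to a common distribution and summarises the probes of each probe set, with no version. Whether the 2 arrays were normalized together is not given in the sources used here. Values ran from 1.89 to 13.7. The values were also deposited in a second table, which differed from the first by 0 in every row, and the authors' log2 ratio column equalled Oasl1-/- minus WT in every row. RMA compresses the differences of dim probe sets, and mixing the RNA before labelling hides the spread between cultures. The number of arrays limits the precision, and no p-value can be had.

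Of the probe sets, 25305 carried 1 gene symbol, 2 carried several and 10249 carried none, and those with several or none were left out of the gene tables. Symbols on the array date from its design and were updated through RefSeq accessions and synonyms of the GRCm38.p6 annotation. The accession matched for 20515 probe sets, a unique synonym for 1236 and the symbol itself for 1840, while 1714 kept the name in the deposited table. This gave 22014 genes, of which 1740 had more than 1 probe set, represented by the one with the highest mean of both arrays. For 309 of the genes above the floor that probe set lies on another chromosome than the gene, at what may be a processed copy, and a run without such probe sets was added after seeing the data. It replaced a run without list members on the mitochondrial genome, also chosen after seeing the data, which altered nothing. Coordinates are those of the deposited table. The transcript descriptions in it name the NCBIM37 build, and 93.0% of 2286 probe sets with such a description overlapped its position.

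The floor of each array was the 95th percentile of its 5267 negative control probe sets (intron and antigenomic background), and comparisons used genes above the floor on at least 1 array. Where a gene was above the floor on 1 array only, its fold is a lower bound, the bright value minus the higher of the floor and the dim value, and where it was below on both no fold is given. Genes at least 2-fold higher or lower were counted. The median difference of each fixed gene list was placed among 10000 random lists of equal size, matched on mean expression in 20 bins. Genes within 10 Mb of Oasl1 were treated the same way with absolute differences. The lists cover interferons, interferon-stimulated genes, OAS genes, sensing, interferon signalling, cytokines, chemokines, NF-kB, GTPases, antigen presentation, macrophage states, proliferation, stress, metabolism, cell death, translation, reference and sex-linked genes, and markers of 11 other cell types.

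The groups, the floor, the thresholds, the lists, the alternatives and the rule for named genes were set before the data were examined, except where the text says otherwise. The rule names Oasl1, the 15 genes with the largest positive and the 15 with the largest negative difference among genes above the floor (predicted or unnamed models, immunoglobulin and T cell receptor segments and small RNAs left out), of each list the members at least 2-fold different (at most 4) or otherwise the 2 with the largest difference, and in any case Ifnb1, Ifna4, Irf3 and Irf7. Other genes given as examples were chosen after their values were seen.

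Alternatives were thresholds of 1.5-fold and 3-fold, no floor, the floor on both arrays, the array median as the floor, differences centred on the median gene, differences with a loess trend removed (span 0.3), quantile normalization, the mean of all probe sets of a gene, the second table, log2 of the linear value plus 32, unmatched random lists, and windows of 5 and 20 Mb. The counting and the list percentiles were tested on simulated data with 6375 genes and noise with an SD of 0.2. Of 200 genes changed by 1.5 (log2), 99.5% were called at least 2-fold different with the right sign, and 0 unchanged genes were called. With noise this small beside the 2-fold threshold, both results were nearly fixed in advance. They check the counting code and not the error rate in these data. Of 200 unchanged lists of 20 genes, 3.0% lay in either tail of 2.5%, and 95.5% of lists shifted by 0.2 lay in the top 2.5%. The simulated noise was independent and had the same SD for all probe sets. In the data the robust SD was 0.07 for genes as bright as Oasl1 and 0.26 for genes as dim as Ifnb1. Members of a real list can also vary together, so the simulation does not check the percentiles of such lists. Computation used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, statsmodels 0.14.6 and Matplotlib 3.10.9.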

Results

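Gene expression was measured in mouse bone-marrow-derived macrophages, the phagocytes that grow out of marrow in medium conditioned by L929 fibroblasts, here over 7 days. Wild-type (WT) cells and cells lacking Oasl1 (Oasl1-/-), both of the C57BL/6J strain, were given 5 µg/ml poly(I:C), a synthetic double-stranded RNA that mimics a viral infection, for 9 h. Total RNA of 3 samples per genotype was mixed and put on an Affymetrix Mouse Gene ST array, so that there was 1 array per genotype, 2 in all, and no array of untreated cells. Each array gave log2 values for the same probe sets. The median value was 5.72 on the WT array and 5.74 on the Oasl1-/- array. A gene counted as above the floor when its value exceeded the 95th percentile of the array's negative control probe sets, which was 7.75 for WT and 7.68 for Oasl1-/-. Of 22014 genes, 6376 were above the floor on at least 1 array and 6007 on both. With 1 array per genotype no difference has a replicate check, and none was tested. Differences are given as Oasl1-/- minus WT on the log2 scale.

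The comparison asked how the loss of Oasl1 alters the transcripts of macrophages responding to double-stranded RNA. OASL1 belongs to the family of oligoadenylate synthetase-like proteins and is known to hold back translation of the mRNA of Irf7, the transcription factor that drives the interferon alpha genes. Oasl1 itself (NM_145209, chromosome 5, positions 115373249 to 115387924 in the NCBIM37 build) had a value of 12.59 on the WT array and 11.13 on the Oasl1-/- array, a difference of -1.46, or 2.76-fold lower. It remained far above the floor in the Oasl1-/- cells. The probe set covers the whole transcript with 29 probes, and which of them lie in the deleted part is not known here, so the remaining signal does not measure the efficiency of the knockout.

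The Oasl1-/- macrophages had higher signals for type I interferon genes, the secreted antiviral cytokines, while nearly every other gene had a similar value on both arrays. At least 2-fold higher in Oasl1-/- by the measured values were 9 genes, all 9 of them type I interferons, namely Ifna15, Ifna6, Ifna2, Ifna1, Ifna7, Ifnab, Ifna14, Ifna5 and Ifnb1. At least 2-fold lower were 5 genes, namely Oasl1, Rnf34, Klra2, Ctla2a and Fpr1. Of the genes above the floor, 99.1% differed by less than 1.5-fold, and their median difference was -0.04.

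**Figure D1:**
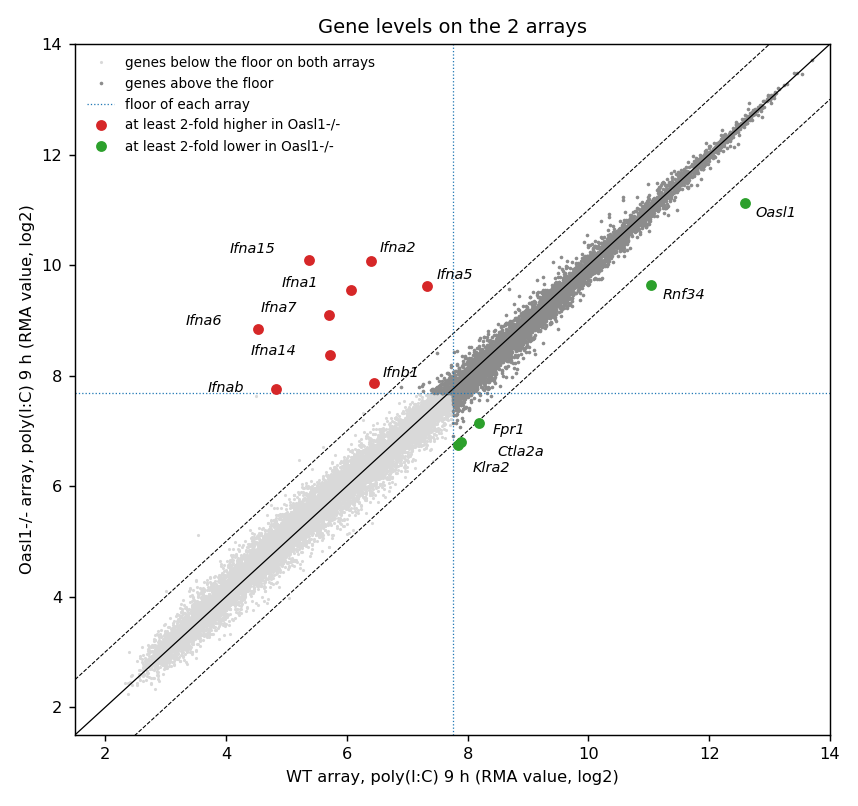
Each point is a gene, with its RMA value (log2) on the WT array on the x axis and on the Oasl1-/- array on the y axis; the solid line marks equal values, the dashed lines a 2-fold difference and the dotted lines the floor of each array. The 9 interferon genes (red) lie left of the WT floor and above the Oasl1-/- floor, and Oasl1 and Rnf34 (green) are the genes above both floors that lie outside the 2-fold lines.

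None of the 9 interferon genes was above the floor on the WT array, so each fold is a lower bound, the Oasl1-/- value set against the WT floor. Ifna15 (NM_206870, chromosome 4, positions 88199349 to 88204149) had values of 5.37 in WT and 10.09 in Oasl1-/- and was at least 5.04-fold higher. Ifna2 had values of 6.40 and 10.07 and was at least 5.00-fold higher. Ifna5 had 7.33 in WT and 9.62 in Oasl1-/-, at least 3.65-fold higher, and Ifna1 had 6.06 and 9.54, at least 3.44-fold higher. Ifna7 had 5.71 and 9.09, at least 2.52-fold higher, and Ifna6 had 4.53 and 8.85, at least 2.14-fold higher. Ifna14 had 5.72 and 8.37, at least 1.53-fold higher. Ifnb1 (NM_010510, chromosome 4, positions 88167929 to 88168698), the interferon beta gene, had 6.45 in WT and 7.87 in Oasl1-/-, at least 1.08-fold higher. Ifnab had 4.83 and 7.76, at least 1.01-fold higher. The measured differences of the 9 genes ran from 1.41 for Ifnb1 to 4.71 for Ifna15.

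Of the 20 type I and III interferon genes on the array, 10 were above the floor on at least 1 array, all 10 of them on the Oasl1-/- array alone. The tenth was Ifnl2, a type III interferon, with 7.36 in WT and 7.89 in Oasl1-/-, at least 1.1-fold higher. The median measured difference of the 10 genes was 3.15, against 1.5 over all 20, and lay at percentile 100 of 10000 random lists of equal size matched on mean expression. The members were picked by the floor through the Oasl1-/- array, so that the median of 3.15 overstates the list. The random lists were drawn from genes above the floor on either array, so the percentile does not test the list. With values below the floor set to the floor, an alternative chosen after seeing the data, the median was 1.22 and 6 genes were at least 2-fold higher. Of the 10 members below the floor on both arrays, Ifna4 had 4.49 in WT and 7.63 in Oasl1-/-, Ifna11 had 3.53 and 5.12, and Ifna9 had 5.20 and 6.47. Ifna12 (3.61 and 3.55), Ifna13 (3.94 and 3.69), Ifna16 (5.77 and 6.06) and Ifne (5.05 and 4.93), which lie in the same cluster on chromosome 4, were near equal on both arrays and below the floor on each. The Ifna genes are close paralogs, and their probe sets can take up each other's transcripts, so the values of single Ifna genes are uncertain.

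**Figure D2:**
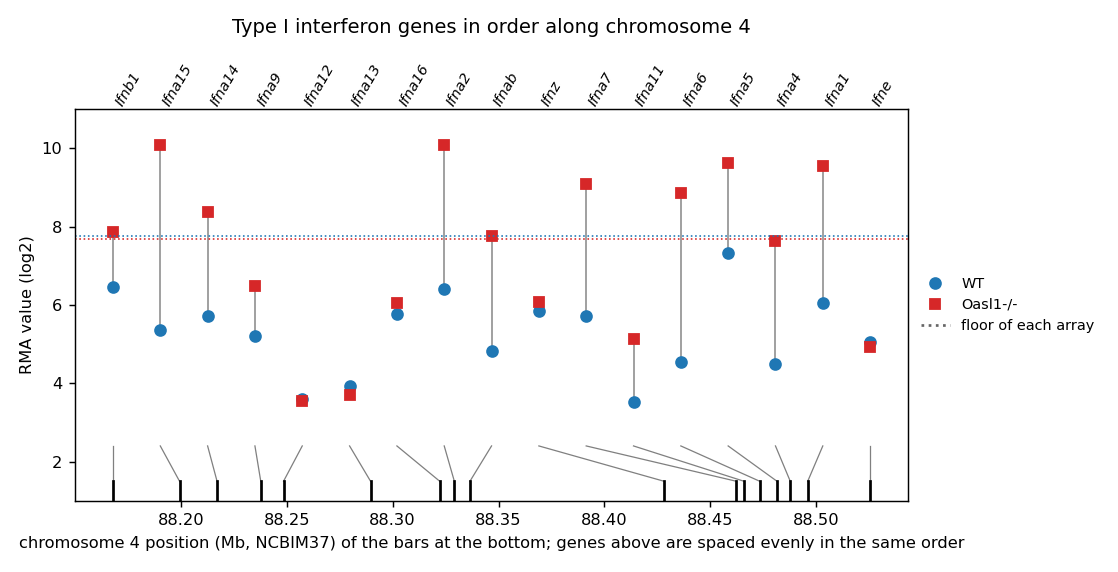
RMA values (log2, y axis) of the type I interferon genes of chromosome 4 on the WT array (blue circles) and the Oasl1-/- array (red squares), spaced evenly in genome order, with the NCBIM37 position of each probe set on the bar at the bottom; dotted lines are the floors at 7.75 and 7.68. Ifna15 has 5.37 in WT and 10.09 in Oasl1-/-, while Ifna12, at 3.61 and 3.55, differs little.

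The transcripts that interferon induces were at a similar, high level in both genotypes. All 44 interferon-stimulated genes of the fixed list were above the floor, and none differed by 1.5-fold or more. Their median difference was 0.04 (percentile 99.1 of the random lists), with 27 genes above 0 and 17 below. The largest differences were those of Ifi27l2a (10.34 in WT, 10.93 in Oasl1-/-, difference 0.58) and of Ch25h, the cholesterol hydroxylase (11.37 and 11.66, difference 0.29). Well-known members such as Isg15 (11.80 and 11.87), Mx1 (11.45 and 11.45) and Rsad2 (13.03 and 13.07) had nearly equal values. Irf7 mRNA was 12.48 in WT and 12.19 in Oasl1-/-, a difference of -0.28. Of the other OAS family genes, 7 were above the floor, with a median difference of -0.07 (percentile 12.3). Oas1c had a difference of -0.34 and Oasl2, the neighbour of Oasl1, one of -0.11.

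The receptors, adaptors and factors that lead to interferon production differed little as well. Of 22 sensing and signalling genes above the floor, none differed by 1.5-fold, and the median was -0.02 (percentile 50.4). Irf3, the constitutive interferon regulatory factor, was 7.95 in WT and 7.81 in Oasl1-/-, and Irf8 was 9.63 and 9.94. The 17 genes of interferon receptor signalling and its feedback had a median of 0.03 (percentile 92.9). Ptpn2, a phosphatase that acts on JAK kinases, had a difference of -0.31 and Socs3, a feedback inhibitor of cytokine receptors, one of 0.29.

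Apart from the interferons, 6 genes had the next largest positive differences by the measured values, all under 2-fold, and for Lcn2 and Ngp, below the floor in WT, the place in that order is not certain. Lcn2, the siderophore-binding lipocalin, was 7.49 in WT, below the floor, and 8.40 in Oasl1-/-, at least 1.56-fold higher. Ngp, a neutrophil granule protein, was 6.90 and 7.79, at least 1.03-fold higher. Glul, glutamine synthetase, had a difference of 0.88 (8.69 and 9.56) at a probe set on chromosome 11, while the probe set on its own chromosome, 1, was below the floor in WT (7.39 and 8.11). Abcg1, a cholesterol exporter, had a difference of 0.65 (10.57 and 11.23). Hcar2, the receptor for nicotinic acid, had a difference of 0.65 (7.78 and 8.42), and Cd5l, a protein secreted by macrophages, one of 0.64 (9.41 and 10.05).

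Among the genes lower in Oasl1-/-, Rnf34, an E3 ubiquitin ligase gene, stood beside Oasl1. Rnf34 (NM_030564, chromosome 5, positions 123300197 to 123318965) was 11.04 in WT and 9.64 in Oasl1-/-, a difference of -1.40, or 2.64-fold lower. These 2 were the only genes above the floor on both arrays that differed by 2-fold or more. Klra2, a receptor of the Ly49 family, was 7.84 in WT and 6.75, below the floor, in Oasl1-/-, at least 1.12-fold lower. Ctla2a, a cysteine protease inhibitor, was 7.89 and 6.80, at least 1.16-fold lower. Fpr1, the formyl peptide receptor, was 8.18 and 7.14, at least 1.41-fold lower. With values below the floor set to the floor, 2 genes were at least 2-fold lower. The other 10 of the 15 genes with the largest negative differences lay between -0.86 and -0.65. Those above the floor on both arrays were Stk17b (-0.74), Lpar6 (-0.72), Fabp7 (-0.70), Fos (-0.66) and Pot1b (-0.65). The rest were below the floor in Oasl1-/-: Zcchc7 (7.76 and 6.90, at least 1.06-fold lower), Adgb (7.87 and 7.07, at least 1.14-fold), Zmym5 (8.32 and 7.56, at least 1.55-fold), Otulinl (7.92 and 7.17, at least 1.18-fold) and Htr2b (7.91 and 7.24, at least 1.17-fold).

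Inflammatory mediators differed in both directions. Of 17 inflammatory cytokine and mediator genes above the floor, 1 was at least 1.5-fold higher (Lcn2) and none lower, and the median was -0.05 (percentile 34.9), against 0.04 over all 28 measured. Ptgs2, the inducible cyclooxygenase, had the next largest difference, 0.53 (10.34 in WT, 10.87 in Oasl1-/-). The 17 chemokine genes had a median of 0.06 (percentile 99.3), with 11 above 0. The largest differences were those of Cxcl2, a neutrophil attractant (9.10 and 8.47, difference -0.63), and Ccl2, a monocyte attractant (9.93 and 10.42, difference 0.49). The 22 genes of NF-kB feedback and early response had a median of -0.04 (percentile 13.1), with Nfkbiz at -0.46 and Traf1 at -0.34. Of 9 immediate early genes above the floor, 6 were lower, with a median of -0.15 (percentile 4.27), against -0.09 over all 23 measured. Fos was 9.25 and 8.59, and Dusp1, a MAP kinase phosphatase, 11.80 and 11.45.

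Genes of antigen presentation and interferon-inducible GTPases had small differences. The 15 guanylate-binding protein and immunity-related GTPase genes had a median of 0.05 (percentile 96.9), with Gbp2 at 0.28 and Gvin1 at -0.21. The 19 genes of MHC class I presentation had a median of 0.00 (percentile 63.5), with Tap2 at 0.16 and Tapbp at 0.11. Of 6 genes of MHC class II presentation above the floor, 5 were higher, with a median of 0.14 (percentile 99.7), against 0.03 over all 12 measured. H2-Eb1 was 9.25 in WT and 9.55 in Oasl1-/-, and H2-Ab1 9.97 and 10.16.

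The cells of both genotypes had the transcripts of macrophages at similar levels. The 28 macrophage identity genes above the floor had a median of 0.01 (percentile 80.1), and none differed by 1.5-fold. Cebpb had the largest difference, -0.32, and Aif1 followed with -0.17. Of 6 genes of alternative activation above the floor, Il4ra, the interleukin 4 receptor chain, had a difference of 0.59 (9.55 and 10.14) and Msr1, a scavenger receptor, one of -0.25. The median of these 6 was 0.03 (percentile 87.5), against 0.21 over all 19 measured, of which 13 were below the floor.

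Markers of other cell types were mostly below the floor on both arrays. None of 14 T cell markers was above it. Of 16 neutrophil and granulocyte precursor markers, 2 were above it, Ngp on the Oasl1-/- array only (6.90 and 7.79, at least 1.03-fold higher) and Csf3r at -0.38, with a median of -0.17 when the bound of Ngp is used. The median over all 16 was 0.17. S100a9 (5.43 and 6.31), S100a8 (6.24 and 6.85) and Elane (4.70 and 5.34) had higher values on the Oasl1-/- array. They were picked, after their values were seen, from the 14 markers not above the floor, and do not stand for the list. Lcn2, also made by neutrophils, was higher on the Oasl1-/- array too, while Csf3r was lower. Of 15 dendritic cell markers, 5 were above the floor, with a median of 0.06 (percentile 92.0), Fscn1 at 0.09 and Cd83 at 0.06. Of the 10 endothelial markers, 2 were above it, Kdr at 0.23 and Eng at 0.19. The B cell list had 1 gene above the floor, Blnk (-0.15), the mast cell and basophil list Hdc (0.32), the erythroid list Tfrc (0.36), the platelet list Pf4 (-0.15) and the osteoclast list Atp6v0d2 (-0.01, and 0.08 with the trend on mean expression removed). Of the NK cell markers, Klrk1 had a difference of -0.15, and the bright Prf1 probe set (12.33 and 12.37) lies on chromosome 1, while the probe set on the chromosome of Prf1, 10, was below the floor (5.86 and 6.49). Cdh11, the stromal marker above the floor, likewise owed its value to a probe set on chromosome 18 (9.89 and 9.78), with 4.87 and 4.85 on its own chromosome, 8. Y-linked Ddx3y (9.68 and 9.40), Uty (8.71 and 8.24) and Eif2s3y (9.30 and 9.11) were above the floor in both genotypes, with a median difference of -0.28, and Xist (4.09 and 3.94) was below it in both.

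Cell division genes were slightly higher in Oasl1-/-, and DNA replication genes differed in both directions. Of 11 cell division genes above the floor, 10 were higher, with a median of 0.08 (percentile 99.4). Ccnb1, which encodes cyclin B, had a difference of 0.27 and Nuf2, a kinetochore component, one of 0.24, the former at a probe set on chromosome 7 that is not its own. Of 22 DNA replication genes, 14 were higher and 8 lower, with a median of 0.04 (percentile 99.2), with Mcm10 at 0.34 and Cdc45, below the floor in WT (7.70 and 7.99), at least 1.18-fold higher. No gene of either list differed by 1.5-fold.

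Cholesterol synthesis and heat shock genes were slightly lower, and genes of the endoplasmic reticulum stress response slightly higher. Of 11 cholesterol synthesis and uptake genes above the floor, 9 were lower, with a median of -0.19 (percentile 1.22), against -0.06 over all 22 measured. Idi1, an isomerase of the pathway, was 8.63 in WT and 8.15 in Oasl1-/-, and Fdft1, squalene synthase, was 8.43 and 8.13. Of 10 heat shock genes, 9 were lower, with a median of -0.13 (percentile 0.50, or 5.89 against random lists not matched on mean expression). Hsph1 (8.90 and 8.52) and Hspd1 (9.86 and 9.49) had the largest differences, both -0.37, the latter at a probe set on chromosome 11 that is not its own. Of 15 genes of the endoplasmic reticulum and integrated stress responses, 10 were higher, with a median of 0.11 (percentile 99.98). Psat1, an enzyme of serine synthesis, had a difference of 0.37 and Sdf2l1, a chaperone component, one of 0.25.

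The remaining lists stayed close to 0. The 18 glycolysis and hypoxia genes had a median of 0.04 (percentile 98.0), with Bnip3 at -0.25, at a probe set on chromosome 14 (on its own chromosome, 7, it was below the floor on both arrays), and Pfkp at 0.23. The 13 genes of LXR targets and lipid handling had a median of 0.03 (percentile 90.9), with Abcg1 at 0.65 and Nr1h3, the receptor LXR alpha, at -0.31. The 13 oxidative stress genes had a median of -0.02 (percentile 59.1), with Srxn1 at -0.34 and Gclm at -0.28. The 21 cell death genes had a median of -0.05 (percentile 29.3), with Nlrp3 at -0.29 and Bcl2l11 at -0.18. The 23 translation initiation genes had a median of -0.06 (percentile 14), with Eif4a2 at -0.41 and Eif3e at -0.27. The 18 reference genes had a median of 0.00 (percentile 58.0), with Tfrc, the transferrin receptor, at 0.36. Of 26 lists with at least 5 members above the floor, 8 lay in the top 2.5% of their random lists and 2 in the bottom 2.5%. Without probe sets off the gene's own chromosome, an alternative chosen after seeing the data, interferon-stimulated genes left the top 2.5% (percentile 97.2) and LXR targets entered it (percentile 97.7). These percentiles describe the 2 arrays, and members of a list that vary together can place it in a tail without any effect of genotype.

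**Figure D3:**
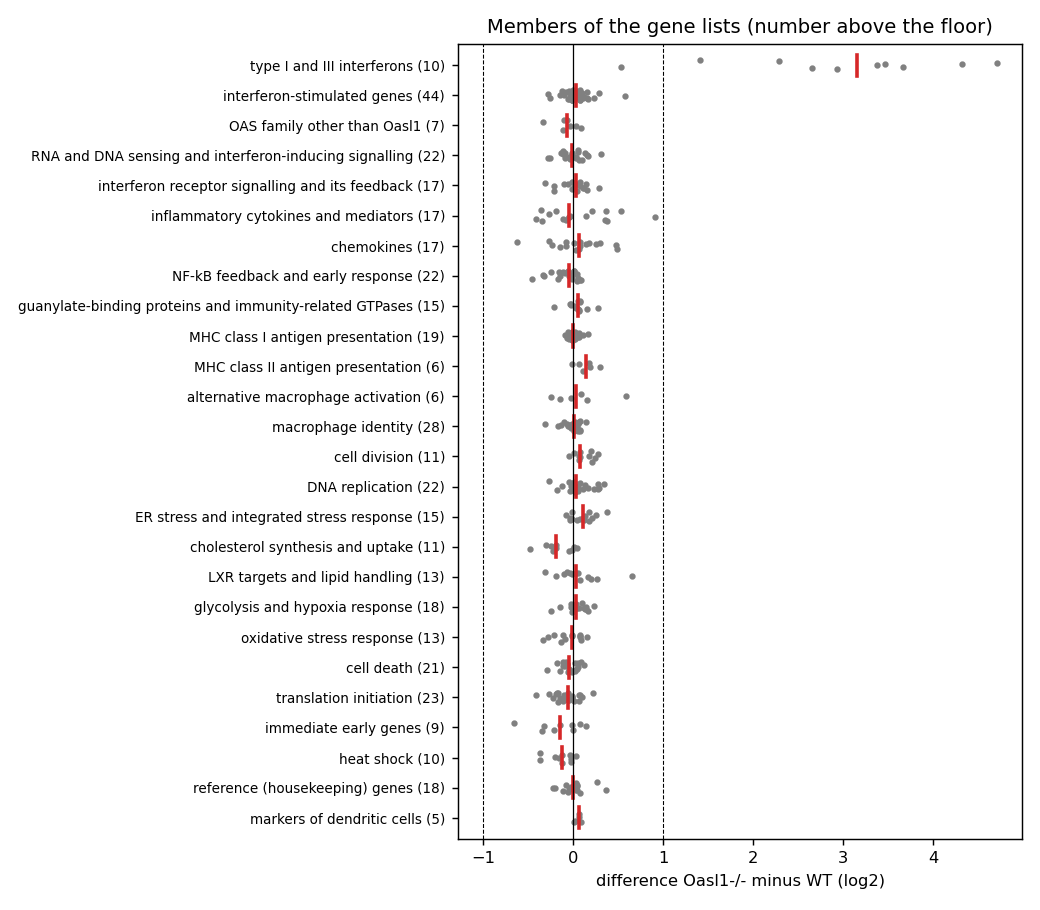
Difference Oasl1-/- minus WT (log2, x axis) of each list member above the floor (grey points, with a vertical jitter) and the median of each list (red bar), for the 26 lists with at least 5 such members; dashed lines mark a 2-fold difference. The type I and III interferons have a median of 3.15 (1.22 with bounds, 1.5 over all 20 measured), and the other medians lie between -0.19 and 0.14.

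Genes near Oasl1 on chromosome 5 were compared because a knockout made in cells of another strain can carry flanking sequence of that strain. The 116 genes above the floor within 10 Mb of Oasl1, Oasl1 left out, had a median absolute difference of 0.123, at percentile 96.5 of the matched random lists, whose median was 0.0996. At least 0.4 in size by the measured values, a mark picked after the values were seen, were 9 of them (7.76%), against 3.07% of all genes above the floor. They were Rnf34 and Hcar2, given above, and, named here after their values were seen, Tmed5 (-0.50), Cmklr1 (-0.48), Gltp (-0.48), Kctd10 (0.43), Cox6a1 (0.43), Fbxo21 and Vps37b. Fbxo21 was below the floor in Oasl1-/- (7.83 and 7.31) and at least 1.11-fold lower, and Vps37b was below it in WT (7.72 and 8.19) and at least 1.35-fold higher. The percentile of the 10 Mb window ran from 84.0 to 98.9 over the alternatives. For the 49 genes within 5 Mb the percentile was 63.2, and for the 165 genes within 20 Mb it was 94.7. The share of genes at least 0.4 in size was 10.2% within 5 Mb (5 genes) and 6.06% within 20 Mb (10 genes).

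**Figure D4:**
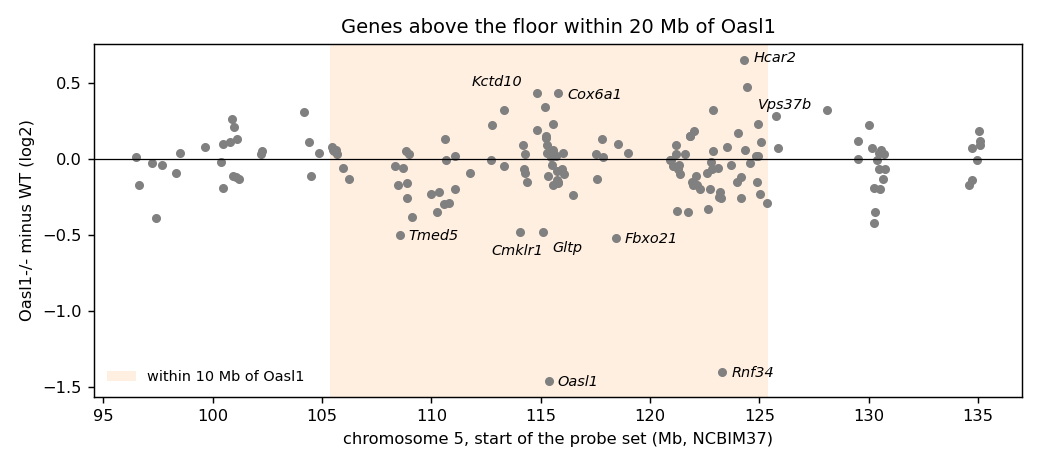
Difference Oasl1-/- minus WT (log2, y axis) of the genes above the floor within 20 Mb of Oasl1, against the NCBIM37 position of the probe set on chromosome 5 (Mb, x axis); the shading marks 10 Mb on either side. Oasl1 at -1.46 and Rnf34 at -1.40 lie apart from the other genes, which are between -0.52 and 0.65.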

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

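All tests in this part were chosen after the result was seen. The antigenomic background probe sets, whose sequences occur in no mouse gene and which the comparison of genotypes used only for the floor, were brighter on the Oasl1-/- array, with a median difference of 0.14 over 45 probe sets (bootstrap interval 0.03 to 0.24). Random lists of ordinary probe sets of like brightness had medians between -0.08 and 0.05, which is why they are listed here. The brighter 23 had a median of 0.27 and the dimmer 22 one of -0.01, and quantile normalization left the median at 0.16.

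The 5222 intron control probe sets went the other way, with medians of 4.79 in WT and 4.54 in Oasl1-/- and a median difference of -0.16, and 432 were at least 2-fold lower against 72 higher. Less unspliced RNA in the Oasl1-/- pool would leave exon controls of like brightness near 0. The 278 exon controls with a mean under 7 had a median of -0.18 (bootstrap interval -0.27 to -0.11), so dim exon controls were lower too. They were brighter in WT (median 5.78) than the intron controls with a mean under 7 (4.56). The 2 sets were not matched on brightness, so this comparison does not decide on unspliced RNA. Noise of probe sets with 4 probes would put the large differences on both sides, while 85.7% of the 504 were lower (Wilson interval 82.4% to 88.5%). This interval and the bootstrap intervals treat probe sets as independent, though all come from the same pair of arrays and can move together. Probe base composition stays open, since the difference of the antigenomic probe sets went with their brightness across probe sets (Spearman rho 0.90, probe sets not being independent replicates) but the base composition of the intron probes was not used here. A biological difference between the genotypes was not tested and stays open. A shift of this size is small beside the measured interferon differences (1.41 for Ifnb1 to 4.71 for Ifna15). It is not small beside the lower bounds of Ifnb1 (0.12) and Ifnab (0.01).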

How the results depend on the processing

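Oasl1 kept its difference under all alternatives run, between -1.47 and -1.42. It has 1 probe set, above the floor on both arrays. The second table, the mean of all probe sets and values set to the floor could therefore not move it, nor could removal of probe sets off its chromosome. The 9 genes at least 2-fold higher became 23 at 1.5-fold, 15 with no floor and 0 when both arrays had to be above the floor, since the WT values of the interferons lie below it. The 5 genes lower became 33 at 1.5-fold, 0 at 3-fold, and 2 with the floor on both arrays, with log2 of the linear value plus 32, and with values below the floor set to the floor. The last setting and the removal of probe sets off the gene's own chromosome were chosen after seeing the data. The interferon list median of 3.15 became 3.26 with the loess trend removed, 2.43 with the offset of 32, 1.22 with values set to the floor and 1.5 with no floor, the last because it adds the members below the floor. The median of interferon-stimulated genes moved from 0.04 to 0.08 on centring. The median absolute difference near Oasl1 moved from 0.123 to 0.108 on centring, 0.110 with loess, 0.105 with quantile normalization, 0.110 with the mean of all probe sets, 0.111 with values set to the floor and 0.109 within 5 Mb, and the cause was not tested. With no floor the medians were 0.06 for chemokines, 0.07 for cell division, 0.02 for DNA replication, 0.07 for endoplasmic reticulum stress, -0.13 for heat shock and 0.03 for glycolysis. Against unmatched random lists the GTPase genes moved from percentile 96.9 to 98.5, into the top 2.5%, and heat shock from 0.50 to 5.89, out of the bottom 2.5%. A test of array scaling as the source of the interferon difference was run, left out to keep to 3 explanations, and supports nothing here, since the scalings shift values too little to have failed it. No gene called beyond 2-fold and no fixed list in a tail of its random lists changed sign. Over all lists, 51 of the medians under alternatives moved by more than the SD of their random lists and 271 did not. Of the values of named genes other than Oasl1, 33 moved by more than the spread of genes of like brightness and 687 did not. The second table, equal to the first, could move nothing and makes up 36 of the 271 and 90 of the 687. No paired analysis was possible because there is 1 array per genotype. Signal over background limits the interferon genes, whose WT signals lie below the floor.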

Other observations

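All tests in this part except that of saturation and the planned 10 Mb comparison, whose limits as a sign of flanking sequence were set later, were chosen after the result was seen. Of 24 genes of the histone clusters above the floor, 22 were higher in Oasl1-/- macrophages, with a median difference of 0.24 (0.22 to 0.29 over the alternatives). H2bc9 was 7.82 in WT and 8.20 in Oasl1-/-, H2bc6 10.00 and 10.37, and H3c7 11.25 and 11.49, while H1f2 was below the floor in Oasl1-/- (7.95 and 7.57) and at least 1.20-fold lower. Of other histone genes under the nucleosome assembly term, H3f3a was at -0.11, H3f3b at -0.02, H2aw at 0.08, Macroh2a1 at 0.12 and H2az1 at 0.27, and H4f16 (7.49 and 7.76) and Cenpa (7.51 and 7.71) were below the floor in WT and above it in Oasl1-/-. The group was formed because nucleosome assembly came out at the top of a scan of annotation terms on the same arrays, itself chosen after the data were seen, and H1f0 (7.87 and 7.82) was taken out after a first run, which left the median the same. The median describes a group picked for its values. Genes of the same histone type are close copies whose probe sets may share transcripts, which was not computed here. The scan held 238 biological process terms of the array's annotation, each with 10 to 200 genes above the floor. Of these terms, 22 lay in the top 2.5% and 13 in the bottom 2.5% of their random lists. In each tail 6 are expected if the genes of a term vary independently. Genes of a term can vary together and terms can share genes, so the excess over 6 does not show an effect of genotype. The 3 highest were nucleosome assembly (41 genes, median 0.19), hemopoiesis (20 genes, 0.08) and protein glycosylation (16 genes, 0.10), and the 3 lowest regulation of cell shape (19 genes, -0.20), chromatin modification (103 genes, -0.13) and mRNA processing (171 genes, -0.09). With the loess trend removed, chromatin modification was at -0.06, mRNA processing at -0.05 and regulation of cell shape at -0.16, and over all alternatives nucleosome assembly ran from 0.12 to 0.23, hemopoiesis from 0.08 to 0.13 and glycosylation from 0.09 to 0.14.

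Of 18 mitochondrial tRNA probe sets, 10 were below the floor on both arrays and 7 above it on both. The 7 had a median difference of -0.37, from -0.62 for tRNA-Glu (9.18 and 8.55) to 0.13 for tRNA-Met (8.85 and 8.97), and 6 of them were lower in Oasl1-/-. Over all 18, those below the floor included, the median was -0.59. The 14 mitochondrial rRNA and mRNA probe sets had a median of 0.01.

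The interferon genes were higher in Oasl1-/- while interferon-stimulated genes differed little. Signal shared between Ifna paralogs stays open, since Ifnb1, whose sequence is far from theirs, had a measured difference of 1.41, beyond the spread of genes of like brightness (robust SD 0.26), but its WT value lies below the floor and its lower bound is 0.12, so that shared signal cannot be told apart from more Ifnb1 transcript. Saturation of bright probe sets would hide a difference in the bright interferon-stimulated genes alone. The 14 with a mean under 11 had a median of 0.01 (bootstrap interval -0.03 to 0.10), so these dimmer genes showed no common shift. How strongly the 14 respond to interferon is not known here, with no array of untreated cells. Saturation of the brighter ones is therefore not excluded. A few plasmacytoid dendritic cells, strong producers of interferon alpha, in the Oasl1-/- pool could raise the Ifna genes, and this cannot be told apart from an effect of genotype, since 2 of 10 markers were above the floor (median of the 10 markers 0.02), Bst2 at 12.02 and 11.96 and Tcf4 at 10.04 and 10.06, both also expressed by other cells, and Siglech was below it (5.23 and 5.39). The hypothesis that loss of OASL1 raises interferon transcripts at 9 h without a matching difference in the transcripts interferon induces stays open and needs replicates.

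The differences around Oasl1, with Rnf34 foremost, may come from flanking sequence of another strain, which can alter expression or the binding of probes. The median absolute difference within 10 Mb was at percentile 96.5, short of the 2.5% tail set for the test. It was above the percentile of 90 under which it would count against, so this median leaves flanking sequence undecided. A median over 116 genes also says little on single large differences, such as that of Rnf34 (-1.40, robust SD of genes of like brightness 0.11). Of 460 overlapping windows of 20 Mb that hold at least 20 genes, 4 span the position of Oasl1. With Oasl1 left out, these 4 ranked from 74 to 147 by median absolute difference. By the share of genes differing by 0.4 or more they ranked from 35 to 47. The mark and the windows were chosen after the values were seen. Neighbouring windows share genes, so the ranks are not those of separate regions. The top window by both measures, on chromosome 4 from 75 to 95 Mb, holds the interferon cluster. The labels give the strain of both genotypes as C57BL/6J, and the origin of the targeted cells was not used here. An effect of Oasl1 loss on Rnf34 itself was not tested.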
